A study of Homo sapiens with 28 samples.

How the data were processed

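RNA was polyA-selected and sequenced as strand-specific libraries from 28 samples of human coronary artery smooth muscle cells, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, Partek and the genome build hg19. The aligner, the gene annotation, the normalisation and the statistical model are not given in the sources used here. Samples were grouped by the siRNA named in their titles, and each control was assigned to the knockdown whose titles spell the replicate in the same way. No sample was left unassigned.

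The authors deposited 1 table of comparison statistics per knockdown, with no per-sample values, so no count model, standard error, replicate spread or split of the samples could be computed. Each row of the deposited tables holds a p-value and a step-up FDR from the authors' test, a ratio of the group means, a signed fold change and the mean of each group. The signed fold change is a score in the sense that the authors wrote a ratio below 1 as its negative inverse. The group means are a normalised signal deposited as least-squares means, whose scale and normalisation are not given in the sources used here. All deposited rows had a p-value of at most 0.05 and an absolute fold change of at least 1.5, which was checked on the files, and the ratio equalled the quotient of the deposited means to within 0.014 on the log2 scale. Because the tables are filtered, an unlisted gene has no value here. The FDR cell is a question mark in 53 distinct rows of the siSUV39H1 table and 53 of the siKDM4A table, as deposited; these stayed missing and such genes were not called.

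Repeated rows were removed, 85 from siSUV39H1, 1 from siKDM4A and 19 from siTET2, which left 1188, 1174 and 5355 distinct rows. Rows whose symbol had been turned into a calendar date, 1 in siKDM4A and 5 in siTET2, were left out of counts of genes. Symbols that are not current were replaced through the RefSeq synonyms where these named a single gene, which updated 54, 43 and 164 symbols; the text prints symbols as the files give them. This updating was part of the plan but took effect only after first counts had been seen, and moved those counts slightly. The siSUV39H1 table has almost no repeated symbol (2 after updating), whereas 183 symbols of siKDM4A and 999 of siTET2 have more than 1 row, which do not name a transcript and whose values can be identical, so that they are not independent. A gene was represented by its row with the smallest p, which gave 1186, 866 and 3675 genes. The number of features the authors tested was derived from the FDR and p of the first row, 18181 for siSUV39H1, about 24900 for siKDM4A and about 25800 for siTET2. The rank of any row was derived as that number times p over FDR. Ranks were read at a p of 0.01, chosen after seeing the data, at the last called row and, for siKDM4A, at a p of 0.0397.

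A gene was called at the authors' FDR under 0.05. The direction of 39 gene lists, fixed before the data were examined together with this test and that of shared directions, was tested with a 2-sided Fisher's exact test of higher against lower genes, list members against all other genes of the same table, called or not, with Benjamini-Hochberg adjustment over the lists with at least 5 listed members. The test asks about direction within the table and is not an enrichment against all expressed genes, and it treats genes as independent. A count adjusted over the list alone could not be computed, since members outside the filtered tables have no p, and an estimated correlation between genes needs per-sample values. Directions of genes called in 2 tables were compared with a 2-sided Fisher's exact test, adjusted over the 3 pairs. Named genes followed a rule fixed at the same point: the 3 targeted genes and KLF4; a set of 15 smooth muscle, matrix, cell cycle and inflammatory genes where listed; the 10 highest and 10 lowest called folds with a second ranking that leaves out the lowest 10% by mean; up to 4 members with the smallest p of each list that passed; and up to 5 genes per direction pattern called in all 3 tables. Some genes the rule selects are not reported here, and other members of the fixed lists are named as examples or exceptions.

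Enriched words were sought in 3′ UTRs from GENCODE 29, whose build is GRCh38 and not the authors' hg19; it was used for names and sequence only, and no coordinates are given. The 3′ UTR of a gene was that of its protein-coding transcript with the longest coding sequence, at least 30 bases long. It was found for 98.7%, 99.2% and 99.4% of the genes of siSUV39H1, siKDM4A and siTET2 that are protein-coding or unmatched in GENCODE. Presence of each 7-base word was compared between lower and higher genes, without the targeted gene, by a Mantel-Haenszel score within 15 bins of length and GC content, and, as a search chosen after the tables had been seen, the highest score was set against the highest of 200 shuffles of direction within bins.

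The list test, the comparison of directions, the rank derivation and the search for words were tested on simulated data. With the real genes and list sizes of siTET2 (3675 genes), 100% of lists moved to mostly higher were recovered and 0.667% of the other lists were called. With those of siSUV39H1 (1186 genes) these shares were 100% and 0%, and with those of siKDM4A (866 genes) 84% and 0.364%, where the 2 lists with the most listed members were moved. Each simulated gene drew its direction independently, so the shares do not cover lists whose genes move together. Independent directions passed 0.05 in 4.4% of 1000 simulations at the 296 genes of siSUV39H1 and siTET2, 0.9% at the 17 of siSUV39H1 and siKDM4A and 3.7% at the 59 of siTET2 and siKDM4A. With 80% of genes set opposite, 100%, 30.4% and 99.8% passed, so the pair with 17 genes had little power. The rank derived from p and FDR was within 1.65% on a simulated table of 18181 features, where the number of features was taken as known. Deriving that number from the first row of a filtered table was not simulated. A word planted in 25% of the lower genes was recovered as the highest word in 20 of 20 simulations of siSUV39H1 (911 genes), 19 of 20 of siKDM4A (793 genes) and 20 of 20 of siTET2 (3390 genes), and a word planted in 12% of them in 12, 10 and 20 of 20. With random directions, 7, 5 and 4 of 100 tables gave a word past 0.05. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives were other thresholds on FDR, p and fold, filters on low means and on ambiguous rows, a rank test with 100000 permutations, and others chosen after seeing the data; a replicate block, leaving out replicates, another normalisation and another pseudocount need per-sample values and were not run.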

Results

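Primary human coronary artery smooth muscle cells, the contractile cells of the wall of the heart's own arteries, were transfected with a small interfering RNA (siRNA) against 1 of 3 chromatin enzymes, and polyadenylated RNA was sequenced. The enzymes were SUV39H1, which methylates lysine 9 of histone H3, KDM4A, which removes methyl groups from that residue, and TET2, which oxidises methylated cytosine in DNA. Each knockdown had its own set of control siRNA samples, matched to it by the wording of the sample titles. The siSUV39H1 comparison held 4 knockdown and 4 control samples, and the siKDM4A and siTET2 comparisons held 5 of each, 28 samples in all. The values analysed were the authors' comparison tables, which give group means, a fold change, a p and a false discovery rate (FDR) for features that passed p of 0.05 and a 1.5-fold change. Depth per sample and the spread between replicates are therefore unknown here, and the error of each fold change is carried only by the authors' FDR. No label says that replicates came from separate cultures or donors, so these FDRs measure only the spread between samples, which may be technical. A gene was called when the authors' FDR was under 0.05, and a gene absent from a table may be unchanged, undetected or changed by less than 1.5-fold.

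The first comparison asks which genes differ when SUV39H1 is depleted. SUV39H1 itself was 4.63-fold lower in the knockdown (normalised means 11.8 and 54.5, FDR 1.85e-11) in the authors' deposited table. KLF4, a transcription factor linked to loss of the contractile smooth muscle state, was 2.80-fold lower (means 40.1 and 112, FDR 2.42e-14) in the authors' deposited table, and its 3′ untranslated region (UTR) holds 2 copies of AGTGGATA, an 8-base word that a search picked from this same table for its excess among lower genes. KDM4A and TET2 are not listed in the authors' deposited table. In total 927 genes were called, of which 275 were higher and 652 (70.3%) lower in the knockdown by the authors' deposited table. At a fold change of at least 2 the count was 309. The FDRs of the authors' deposited table imply that 3965 of 18181 features were under 0.05, of which the 1.5-fold filter left 23.4%, so the count and its share of lower genes describe only part of them.

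Contractile smooth muscle genes rose after SUV39H1 knockdown: 5 of 28 list members were listed, all 5 were called and all were higher, against 29.6% higher among the other genes of the table (Fisher's exact test, adjusted p = 0.00824). MYH11, the smooth muscle myosin heavy chain, was 2.29-fold higher and CNN1, the actin-binding protein calponin, 1.84-fold higher in the authors' deposited table. NEXN (1.5-fold), PDLIM3 (1.71-fold) and ITGA8 (1.51-fold) were the other listed members, all higher by the authors' deposited table. ACTA2, TAGLN, MYOCD, LMOD1 and SRF are not listed there.

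The few listed cell cycle genes were also higher. Of the 64 members of the G2 and mitosis list, 8 were listed, all higher, and 7 of them were called (Fisher's exact test, adjusted p = 0.000853). The mitotic cyclin CCNA2 was 1.52-fold higher, the spindle proteins NUSAP1 and DLGAP5 were 1.58-fold and 1.51-fold higher, and the cohesin acetyltransferase ESCO2 was 1.59-fold higher in the authors' deposited table. Of the 50 members of the S phase list, 7 were listed, all higher, and 5 were called (Fisher's exact test, adjusted p = 0.00145). Among the called were the helicases BRIP1 (1.61-fold) and BLM (1.54-fold), the transcription factor E2F1 (1.51-fold) and the polymerase subunit POLE2 (2.19-fold) in the authors' deposited table. The S phase list had too few members to test at an FDR under 0.01 or without the genes of lowest mean. Of 65 interferon stimulated genes 9 were listed, of which 8 were higher, 5 of them called (Fisher's exact test, adjusted p = 0.00189). The direction of the unlisted members of these lists is unknown. The guanylate-binding proteins GBP1 and GBP2 were 2.01-fold and 2.22-fold higher, the immune checkpoint ligand CD274 1.63-fold and the antiviral GTPase MX1 4.06-fold higher in the authors' deposited table.

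Genes for secreted signals were among those that fell, although the lists that hold them did not differ from the rest of a table in which 70.3% of called genes were lower. Of the inflammatory cytokine and NF-kB list, all 13 listed members were called, 11 lower and 2 higher (Fisher's exact test, adjusted p = 0.639). CXCL3 was 5.08-fold lower with the smallest p of any gene named for this comparison, IL6 2.75-fold lower and PTGS2, the inducible cyclooxygenase, 3.30-fold lower, whereas the adhesion molecules ICAM1 (2.53-fold) and VCAM1 (1.76-fold) were higher in the authors' deposited table. Growth factors and receptors were lower for 12 of 14 called members (17 listed, Fisher's exact test, adjusted p = 0.658), including the epidermal growth factor receptor ligands EREG (2.81-fold) and AREG (5.14-fold) in the authors' deposited table. All 9 listed vasoactive receptors and their regulators were called and lower (Fisher's exact test, adjusted p = 0.151). Of the collagen list, 4 of 5 called members were higher (Fisher's exact test, adjusted p = 0.0847), and COL1A1, the main fibrillar collagen chain, was 1.87-fold higher in the authors' deposited table. The 3′ UTRs of CXCL3 (673 bases) and EREG (3943 bases) hold a 7-base part of the word found in KLF4, picked in the same way. A longer 3′ UTR has more room to hold a word by chance. Of the 14 lists tested in this table, 4 passed, and the test treats the genes of a list as independent.

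Among single genes, those with the highest folds in the authors' deposited table included TSPAN2, a smooth muscle tetraspanin (8.22-fold higher, means 123 and 15.0), the acute phase gene SAA2 (7.44-fold, means 18.1 and 2.43), C4orf26 (7.21-fold), ZCCHC5 (6.56-fold), SLC7A14 (4.61-fold, means 433 and 93.8) and HOPX, a homeodomain cofactor (4.27-fold). Reads of SAA2 are shared in part with its near-identical neighbour SAA1, so its value is uncertain. Those with the lowest included the read-through locus DYX1C1-CCPG1 (14.0-fold lower, means 1.8 and 25.2, uncertain because it overlaps the genes it joins), the imprinted GTPase gene DIRAS3 (8.66-fold), hepatocyte growth factor HGF (7.87-fold, means 55.9 and 440), the ephrin receptor EPHA7 (6.25-fold), the monocarboxylate transporter SLC16A6 (6.16-fold) and the pyruvate dehydrogenase kinase PDK4 (6.09-fold) in the authors' deposited table. The 3′ UTR of DIRAS3 holds the 8-base word found in KLF4, and that of HGF (3573 bases) holds neither it nor its 7-base parts.

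The second comparison asks the same of KDM4A. KDM4A was 9.0-fold lower in its knockdown (means 3.54 and 31.9, FDR 7.54e-09) in the authors' deposited table, and SUV39H1 and TET2 are not listed there. This table has several rows for many symbols, which appear to be transcripts, and each gene was read from its row with the smallest p. Of 866 listed genes only 123 were called, 38 higher and 85 (69.1%) lower, by the authors' deposited table. Without the FDR criterion 52.2% of the listed genes were lower. The FDRs of the authors' deposited tables imply that about 527 of 24900 features had a p of at most 0.01 in siKDM4A, where chance alone would give 249. In the other tables the same reckoning gave 3901 features against 182 for siSUV39H1 and 5920 against 258 for siTET2. The excess in siKDM4A did not extend to weaker p-values. At a p of at most 0.0397 about 989 features (3.97%) were implied, which is about what chance alone would give. The list tests of this comparison use all 866 listed genes, called or not. Of the features under an FDR of 0.05 the filter left 99.8% in siKDM4A.

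Mitotic genes fell together in the KDM4A knockdown. Of the 64 members of the G2 and mitosis list 40 were listed, all 40 were lower and 19 were called, against 50.1% higher among the other genes (Fisher's exact test, adjusted p = 2.85e-11). The proliferation antigen MKI67 was 45.6-fold lower (means 0.496 and 22.6) and 11.1-fold lower in its other called row, which has the higher mean, the topoisomerase TOP2A 11.2-fold (means 4.29 and 47.9), the kinetochore protein CENPF 7.64-fold and the survivin gene BIRC5 10.7-fold lower in the authors' deposited table. With only genes under an FDR of 0.01 the list did not pass (exact adjusted p = 0.104). All 9 listed S phase genes were lower, but only the ribonucleotide reductase subunit RRM2 was called (12.2-fold lower; Fisher's exact test on the list, adjusted p = 0.0174), by the authors' deposited table. CDC6 and TK1 were listed 5.16-fold and 6.54-fold lower with FDRs of 0.105 and 0.125 in the authors' deposited table. The S phase result did not pass without the genes of lowest mean (exact adjusted p = 0.0590). Processed pseudogenes of cell cycle genes were also listed, RRM2P3 12.5-fold and CDC20P1 10.9-fold lower in the authors' deposited table, and reads may be divided between these and RRM2 and CDC20, whose folds are uncertain for that reason.

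Matrix glycoproteins went the other way. Of the elastic fibre, proteoglycan and matrix glycoprotein list, 13 members were listed and 11 of them were higher (Fisher's exact test, adjusted p = 0.0312), and 5 were called higher and 1 lower. Fibronectin FN1 was 3.13-fold higher (means 1350 and 433), the small proteoglycans LUM and DCN were 5.12-fold and 4.86-fold higher, and the basement membrane protein NID2 was 3.95-fold lower in the authors' deposited table. Read from the row with the highest mean, FN1 (1.85-fold higher, FDR 0.703) and DCN (2.15-fold higher, FDR 1.0) were not called, nor was HLA-C (2.01-fold higher, FDR 0.228) of the interferon list, in the authors' deposited table. TNXB (9.25-fold higher) shares sequence with its pseudogene copy and is uncertain, and FBLN2 was 3.30-fold higher in the authors' deposited table. A permutation test of ranks did not pass for this list (adjusted p = 0.0832). All 4 listed fibroblast markers were higher in the same comparison, LUM and DCN among them as the called ones, too few for a list test. All 14 listed interferon stimulated genes were higher (Fisher's exact test, adjusted p = 0.000188), but only HLA-C was called, at 2.49-fold in the authors' deposited table; HLA genes share reads among themselves, so this value is uncertain. SAMD9 (2.23-fold higher) and IFIT2 (3.26-fold) had FDRs of 0.158 and 0.180 in the authors' deposited table. Of the 13 lists tested 4 passed, and no list passed when only genes with FDR under 0.01 were used, where the S phase, interferon and matrix lists had too few members to test. Among called genes alone the S phase and interferon lists were too short as well.

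None of the 4 listed contractile genes was called in this knockdown. KLF4 was listed with 3 rows, 2.96-fold to 4.15-fold higher at FDRs of 0.443 to 0.816, in the authors' deposited table. ACTA2 was 2.11-fold higher (FDR 0.692), MYOCD, the master cofactor of contractile genes, 7.68-fold lower (FDR 0.254), the cell cycle inhibitor CDKN1A 1.8-fold higher (FDR 0.208) and COL1A1 2.14-fold to 4.88-fold higher over 4 rows (FDR 0.193 to 0.988) in the authors' deposited table. The inflammatory cytokine IL6 was 4.16-fold lower and IL11 5.43-fold lower, and both were called; their list as a whole had 11 of 13 listed members lower (Fisher's exact test, adjusted p = 0.0534), by the authors' deposited table.

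The largest single rises in the authors' deposited table included the histone chaperone gene NAP1L1 (53.5-fold, means 20.2 and 0.378), ISLR (18.5-fold), the lubricin gene PRG4 (17.0-fold), the secretogranin SCG2 (13.9-fold) and TMEM119 (11.8-fold). A second row of NAP1L1 was 3.47-fold lower (means 43.7 and 152, FDR 0.00336) in the authors' deposited table, so the gene as a whole has no single direction. The largest falls included the mitotic genes DLGAP5 (20.8-fold), PBK (13.7-fold) and CDC20 (11.3-fold) in the authors' deposited table. The genes with the smallest FDRs were MOB1A (8.62-fold lower), EDEM1 (6.02-fold) and ARF4 (5.03-fold), which were named after their values were seen, in the authors' deposited table. The 3′ UTRs of EDEM1 (4039 bases) and ARF4 (849 bases) hold a 7-base part of ACCAATTA, and that of MOB1A (4040 bases) holds none. This word was picked from this table for its excess among lower genes.

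The third comparison asks the same of TET2, whose transcript was 2.62-fold lower in its knockdown (means 151 and 394, FDR 1.87e-20) in the authors' deposited table. SUV39H1 was 1.62-fold higher (FDR 0.0378) and KLF4 3.09-fold lower (means 82.9 and 256, FDR 1.42e-04) in the authors' deposited table, which does not list KDM4A. This was the longest table, with 3675 genes and 2899 called, 1168 higher and 1731 (59.7%) lower by the authors' deposited table. At a fold change of at least 2 the count was 1779, and 1931 when symbols with several rows or non-coding names were left out. The FDRs of the authors' deposited table imply that about 6150 features were under 0.05, of which the filter left 66.6%. As for siKDM4A, several rows share a symbol, and 131 symbols had rows in both directions.

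The listed contractile genes mostly fell after TET2 knockdown. Of the 28 list members 17 were listed, and all 17 were called, 16 lower and 1 higher (Fisher's exact test, adjusted p = 0.00905). TAGLN, MYOCD and SRF are not listed in this comparison. ACTA2, smooth muscle actin, was 3.84-fold lower (means 2690 and 10300), MYH11 9.48-fold (means 11.7 and 111), CNN1 2.12-fold and the actin nucleator LMOD1 2.81-fold lower in the authors' deposited table. ITGA8 (12.9-fold), CALD1 (2.57-fold), TPM1 (2.08-fold) and SYNPO2 (4.00-fold) had the smallest p values of the list, all lower, and SMTN was the exception at 2.42-fold higher in the authors' deposited table. All 8 listed endothelial markers were higher in the same comparison, and no value here separates other cells in the cultures from expression by the smooth muscle cells. At an FDR under 0.01 the contractile, collagen and p53 target lists each missed the threshold (exact adjusted p = 0.0554). Markers of the synthetic or modulated state were lower as well, for all 17 listed members, 16 called (Fisher's exact test, adjusted p = 0.00180), including FN1 (4.21-fold, means 3400 and 14300), COL8A1 (2.81-fold), LUM (5.94-fold) and KRT18 (7.21-fold) in the authors' deposited table. SPP1, osteopontin, was 3.58-fold lower at an FDR of 0.0571 and was not called in the authors' deposited table.

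Extracellular matrix genes followed. The collagen and matrix glycoprotein lists share members with the synthetic list, among them COL8A1, FN1 and LUM. Their results are therefore not independent of it. Of the collagen list 17 members were listed, 16 lower and 1 higher, and 14 were called (Fisher's exact test, adjusted p = 0.00905). COL1A1 was 3.16-fold lower (means 36900 and 116000), COL3A1 3.04-fold lower and the basement membrane chains COL4A1 and COL4A2 were 1.64-fold and 1.72-fold lower in the authors' deposited table. COL11A1, the member read as higher (9.61-fold), had other rows 9.42-fold and 10.4-fold lower in the authors' deposited table. Of the elastic fibre, proteoglycan and matrix glycoprotein list 28 of 31 listed members were lower (Fisher's exact test, adjusted p = 0.00203), with HAPLN3 6.54-fold, LOXL4 5.31-fold and EFEMP1 2.47-fold lower in the authors' deposited table. As for the contractile genes, no value here separates other cells in the cultures from the smooth muscle cells for these matrix genes. The collagen result did not pass a permutation test of ranks (adjusted p = 0.206).

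Transcripts of sterol and fatty acid synthesis genes were lower as a block. Of the 35 members of the cholesterol and fatty acid synthesis list 29 were listed, all lower, and 28 were called (Fisher's exact test, adjusted p = 1.14e-05). HMGCS1, which makes the precursor of mevalonate, was 5.87-fold lower (means 372 and 2180), the late-pathway enzyme DHCR7 was 2.90-fold lower, and SREBF2, the transcription factor that drives the pathway, was 2.01-fold lower in the authors' deposited table. Genes of the p53 target list were lower in 15 of 16 listed members, all of them called (Fisher's exact test, adjusted p = 0.0136), with TP53INP1 2.74-fold, BTG2 2.56-fold, GADD45A 1.70-fold, SESN1 12.8-fold and CDKN1A 1.79-fold lower in the authors' deposited table. The apoptosis gene BAX was the member read as higher (1.84-fold), with another row 8.84-fold lower in the authors' deposited table. This list did not pass a permutation test of ranks (adjusted p = 0.186).

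Cell cycle genes rose in the TET2 knockdown. Of the G2 and mitosis list 40 members were listed, all higher, and 32 were called (Fisher's exact test, adjusted p = 3.05e-15). The mitotic activator CDC20 was 3.24-fold higher (means 212 and 65.5), the kinase PLK1 4.67-fold, the phosphatase CDC25B 5.02-fold and the kinesin KIF20A 3.25-fold higher in the authors' deposited table. The row of CDC25B with the highest mean was not called (2.40-fold higher, FDR 0.0691) in the authors' deposited table. S phase genes were higher in 15 of 17 listed members (Fisher's exact test, adjusted p = 0.000618), and of 14 called members 12 were higher and 2 lower. Those called higher included ATAD2 (1.87-fold), CLSPN (5.22-fold) and SLBP (4.68-fold) in the authors' deposited table. The exceptions were TYMS and the replication clamp PCNA, the latter with rows 6.61-fold and 2.22-fold lower in the authors' deposited table.

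Inflammatory genes and endothelial markers were higher. Of the inflammatory cytokine and NF-kB list all 19 listed members were called, 15 higher and 4 lower (Fisher's exact test, adjusted p = 0.00326). IL1B was 9.54-fold higher (means 76400 and 8000), IL1A 7.98-fold, TNFAIP3, a feedback inhibitor of NF-kB, 2.74-fold and ICAM1 3.65-fold higher in the authors' deposited table. Of 18 endothelial markers 8 were listed, all called and higher (Fisher's exact test, adjusted p = 0.00326). The transcription factor SOX17 was 3.02-fold higher (means 1520 and 502), EGFL7 1.93-fold, the endothelial cadherin CDH5 2.27-fold (means 1430 and 628) and the growth factor receptor KDR 2.35-fold higher in the authors' deposited table. PECAM1 was 3.16-fold higher at low means of 58.2 and 18.4 in the authors' deposited table. These markers were not absent from the control cultures, as the means of SOX17 and CDH5 show, and moved in the same comparison in which contractile and matrix genes were lower. Whether another cell type in the cultures or the smooth muscle cells themselves expressed them was not resolved, so the folds describe whole cultures. Fibroblast markers went both ways, 3 higher and 4 lower (Fisher's exact test, adjusted p = 1). Of 33 lists tested 10 passed in this table.

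The highest single folds rested on rows with control or knockdown means near 0. NXF1 (113-fold higher, control mean 0.706), VPS45 (108-fold), PSG1 (101-fold) and CELF1 (101-fold) led the rises, and C19orf44 (222-fold lower, means 0.173 and 38.5), CARD8 (160-fold), LSM5 (131-fold), DERA (127-fold) and LPPR4 (123-fold, means 2.30 and 284) led the falls in the authors' deposited table. LPPR4 had a signed fold of −29.6 in its row with the highest mean in the authors' deposited table. In their rows with the highest mean, NXF1 (1.56-fold), VPS45 (1.79-fold) and CELF1 (2.15-fold) were lower and CARD8 was 2.28-fold higher, all called in the authors' deposited table, so these genes as a whole have no single direction. PSG1 belongs to a family of near-identical genes and is uncertain. The gene with the smallest p was TMEM181, 4.59-fold lower (means 365 and 1680), named after its value was seen, in the authors' deposited table. Its 3′ UTR (3540 bases) holds GAGGGTAA, an 8-base word picked from this same table for its excess among lower genes.

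**Figure D1:**
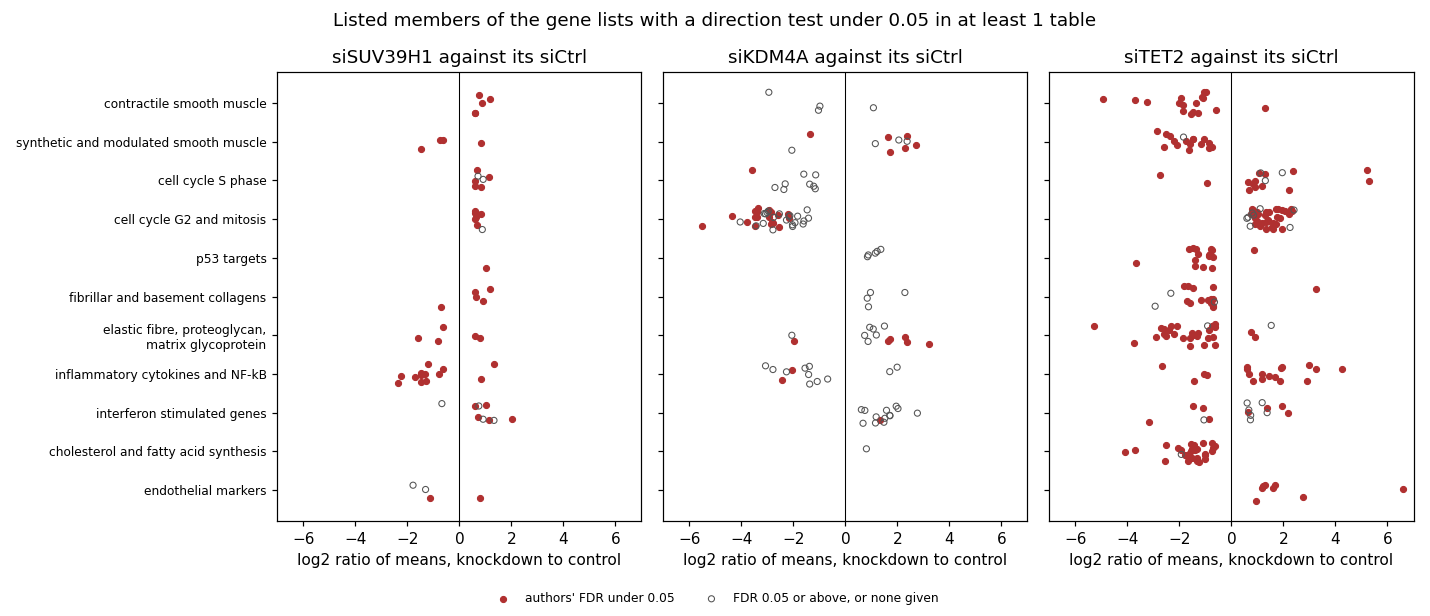
Each point is 1 listed member of a gene list (rows) in the authors' deposited table of each knockdown (panels), at its log2 ratio of group means, knockdown to control; filled points have the authors' FDR under 0.05 and open points do not. All 40 listed G2 and mitosis genes lie left of 0 in siKDM4A and all 40 lie right of 0 in siTET2, and the 29 cholesterol and fatty acid synthesis genes lie left of 0 in siTET2.

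The last comparison asks whether genes called in a pair of knockdowns moved the same way. Between siSUV39H1 and siTET2, 296 genes were called in both by the authors' deposited tables, 148 in the same and 148 in opposite directions, which gave no association (Fisher's exact test, p = 0.536, adjusted p over the 3 pairs 0.536). Between siSUV39H1 and siKDM4A 17 genes were called in both, 5 in the same direction (Fisher's exact test, p = 0.515, adjusted p = 0.536). Between siTET2 and siKDM4A 59 genes were called in both, of which 10 moved the same way and 49 the opposite way (Fisher's exact test, p = 3.63e-08, adjusted p = 1.09e-07). Of these, 24 were higher in siTET2 and lower in siKDM4A, and 25 were lower in siTET2 and higher in siKDM4A. The Spearman correlation of the log2 ratios across these 59 genes was −0.75, which describes genes, not replicates. The tests of shared directions, here and where genes are left out, likewise count genes and treat them as independent. The first set included MKI67 (2.96-fold higher in siTET2, 45.6-fold and 11.1-fold lower in 2 rows of siKDM4A) and CDC20 (3.24-fold and 11.3-fold), and the second FN1 (4.21-fold lower and 3.13-fold higher) and LUM (5.94-fold and 5.12-fold) by the authors' deposited tables. All 14 rows of FN1 in siKDM4A were higher, but only 4 were called, and the row with the highest mean was not. The control sets were separate by the sample titles, and how the tables were normalised is not given, so directions were compared and means were not.

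**Figure D2:**
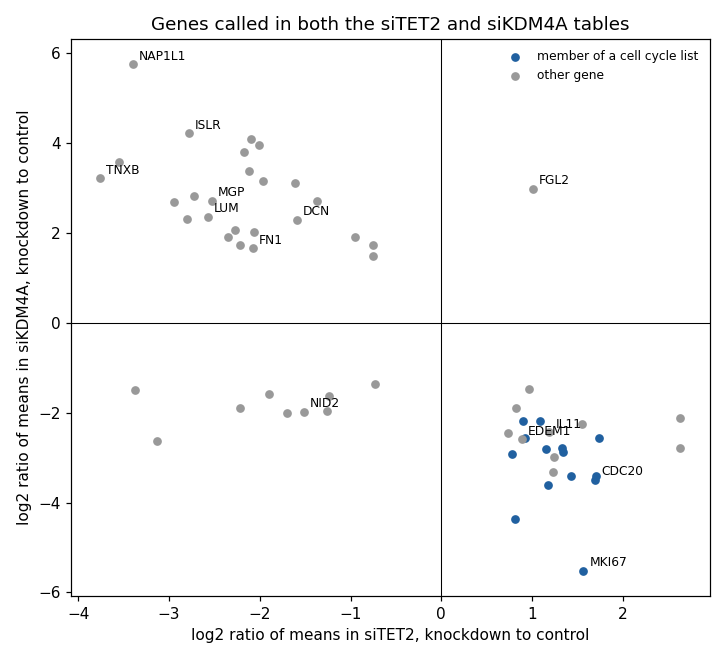
Each point is 1 of the 59 genes called in both the siTET2 and the siKDM4A tables of the authors, at its log2 ratio of group means in siTET2 (horizontal axis) and in siKDM4A (vertical axis), with members of the cell cycle lists in blue. Of the points, 49 lie in the upper left and lower right quadrants and 10 in the others.

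Called in all 3 tables were 12 genes. The mitotic genes CCNA2 and DLGAP5 were higher in siSUV39H1 and siTET2 and lower in siKDM4A, with CCNA2 at 1.52-fold, 1.87-fold and 4.57-fold in the authors' deposited tables. TNXB, uncertain for the reason given above, PRG4, ABCA9 and CST1 were among 8 genes that were lower in siSUV39H1 and siTET2 and higher in siKDM4A. PRG4 was 2.49-fold lower, 4.29-fold lower and 17.0-fold higher in the authors' deposited tables. At an FDR under 0.01, CCNA2, TNXB, PRG4 and ABCA9 were not called in siKDM4A, nor were PRG4 and CST1 in siTET2. FGL2 was lower in siSUV39H1 (3.43-fold) and higher in siKDM4A (7.86-fold) and siTET2 (2.01-fold), and the cytokine IL11 was lower in siSUV39H1 (4.77-fold) and siKDM4A (5.43-fold) and higher in siTET2 (2.28-fold) in the authors' deposited tables. The siTET2 row of IL11 with the highest mean was not called (5.46-fold higher, FDR 0.0592) in the authors' deposited table.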

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

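Alternatives that leave out genes listed in both directions, members of the cell cycle lists or genes holding an enriched word, that use called genes only for the lists, that count each distinct row, or that read each gene from its row with the highest mean were chosen after seeing the data; the others were planned. No count, list or shared direction reversed under the alternatives run. Read from the row with the highest mean, 5 of 228 values of named genes reversed: NAP1L1 in siKDM4A (signed fold −3.47) and NXF1 (−1.56), VPS45 (−1.79), CELF1 (−2.15) and CARD8 (2.28) in siTET2 by the authors' deposited tables. Another 5 were no longer called, as given beside them, and 22 of 203 called values of named genes were not called at an FDR under 0.01. Of all called genes, 2 of 123 in siKDM4A, 38 of 2899 in siTET2 and 0 of 927 in siSUV39H1 reversed when read from the row with the highest mean. At an absolute fold change of at least 2 the called genes were 309 for siSUV39H1 (78.3% lower) and 1779 for siTET2 (64.6% lower). For siKDM4A the count was 72 at an FDR under 0.01, 866 at a raw p under 0.05 (52.2% lower) and 70 without symbols that share rows or have non-coding names, and for siTET2 the last of these gave 1931. Fewer genes enter by construction, except at the raw p. No gene list passed in siKDM4A at an FDR under 0.01 (0 lists). Of 119 alternatives for the 18 results of lists that passed, 111 kept direction and side of the threshold and 8 fell short of it, as given beside those lists; the cause was not tested. A further 7 could not be tested because the list had too few members, and the 18 at a 1.5-fold change left the tables as they are. The opposite directions of siTET2 and siKDM4A kept an exact p under 0.05 in all 7 alternatives, with 7.69% to 22.2% of genes in the same direction. The 7.69% came from leaving out genes holding an enriched word, which tends to remove genes lower in both knockdowns. No paired analysis was possible because the tables hold group means only. A replicate block, leaving out replicates in turn, DESeq2 and another pseudocount were not run for the same reason. Depth is unknown, so what it limits was not assessed.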

Other observations

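The genes of the opening paragraphs were chosen after their values were seen. In siSUV39H1, 4 DNA methylation enzymes were listed and all were called higher, too few for a list test. They were the methyltransferase DNMT3B (1.97-fold), the methylcytosine oxidase TET1 (1.55-fold), the thymine glycosylase TDG (1.58-fold) and IDH2 (1.54-fold) in the authors' deposited table. In the same table TGFB2 was 2.81-fold higher (means 4308 and 1531) and the chromatin protein HMGA2 3.17-fold higher, while BMP2 (2.75-fold), LIF (2.79-fold), the activin antagonist FST (2.29-fold) and the immediate early gene EGR1 (2.88-fold) were lower in the authors' deposited table.

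In siTET2 the cholesterol exporters ABCA1 (3.71-fold) and ABCG1 (40.2-fold, means 86.1 and 2.14) were higher, whereas the scavenger receptor CD36 was 5.22-fold lower in the authors' deposited table; their list of cholesterol efflux and lipid handling had 2 of 7 members higher (Fisher's exact test, adjusted p = 0.807). Collagenase MMP1 was 2.80-fold higher, MMP3 9.24-fold and MMP10 3.70-fold higher in the authors' deposited table; the list of matrix proteases and inhibitors had 11 of 19 members higher (Fisher's exact test, adjusted p = 0.388). Of the 12 members of the small RNA silencing list 3 were listed, too few for a list test in a table with 2899 called genes: AGO2 (2.55-fold), DICER1 (1.93-fold) and TNRC6B (1.69-fold) were called higher in the authors' deposited table. In siKDM4A the activin subunit INHBA (2.78-fold) was lower and the calcification inhibitor MGP was 6.50-fold higher in the authors' deposited table.

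Of the tests that follow, those of base composition and of KLF4 were chosen after the result was seen, as was the search for words itself; the others were set down before their own results were seen. In each table the highest-scoring 7-base word was more frequent in the 3′ UTRs of lower than of higher genes: GTGGATA in siSUV39H1 (score 5.15, highest of 200 shuffles 4.85), ACCAATT in siKDM4A (8.79 and 5.18, with the overlapping CCAATTA at 6.46) and GAGGGTA in siTET2 (6.14 and 4.62). Length and base composition of the 3′ UTR are argued against, since the permutation p within bins of both was 0.005 in each table, the smallest that 200 shuffles can give. A word general to genes that fall in these cells is argued against as well, because 0 of 6 combinations of a word with another table reached a nominal p under 0.05. A sequence-directed effect of each siRNA outside its target may account for part of the lower genes: 3 of 3 targeted mRNAs hold the word of their own table, which transcripts of like length do in 12.3%, 16.1% and 26.5% of cases (joint chance 0.00525), although only 1 of the 3, that of TET2, holds the 8-base word. The siRNA sequences were not used here, among called genes of siKDM4A the word ranked only 3 (score 2.99), and most lower genes carry neither this word nor the one overlapping it (AGTGGAT, CCAATTA, and AGGGTAA at rank 5 and 3.54), since 25.1%, 42.3% and 14.8% hold either in siSUV39H1, siKDM4A and siTET2, against 8.30%, 10.3% and 7.62% of higher genes.

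KLF4, lower in siSUV39H1, has both copies of AGTGGATA within a 3′ UTR of 899 bases. The longest SUV39H1 mRNA holds 1 copy of GTGGATA but 0 copies of AGTGGATA, and AGTGGAT was not sought in it. The match between KLF4 and the targeted mRNA was thus seen for the 7-base word only. The 7-base word GTGGATA was present in 4.15% of higher genes, a share that is not independent of the search, which picked the word for its excess among lower genes, KLF4 included; among 2036 genes of like 3′ UTR length outside the 3 tables it was 2.60%, with 0.786% holding the 8-base word and 0% holding 2 copies (0 allows up to 0.147%), and a search without KLF4 gave the same word (score 5.10, highest shuffle 4.96). A direct effect of the siRNA on the KLF4 transcript and an effect through loss of SUV39H1 cannot be told apart here, because both come with the same siRNA. KLF4 was also lower in siTET2, where its 3′ UTR holds no enriched word of that table, so a lower KLF4 level also occurred without such a word. A second siRNA against SUV39H1 would separate these explanations.

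Of the 59 genes called in both siTET2 and siKDM4A, 49 moved in opposite directions. The members of the cell cycle lists alone are argued against as the whole cause, because without them 35 of 45 genes still moved oppositely (Fisher's exact test, p = 0.000244). Of these 35, 25 were lower in siTET2 and higher in siKDM4A, and 10 the reverse. Genes of cell division outside the lists, TRIP13, GTSE1 and SHCBP1, remained among the 10, so cell division as a whole was not left out. Without genes holding an enriched word, 36 of 39 moved oppositely (Fisher's exact test, p = 7.98e-08). The opposite directions therefore did not rest on those genes alone. The words were picked from these same data for their excess among lower genes. Leaving out their holders thus tends to remove genes lower in both knockdowns, 9 before and 2 after. For that reason this share of opposite genes cannot weigh sequence-directed effects, and indirect effects on genes without a word were not tested. A difference in growth state between knockdown and control cultures, or between the control sets, may still set both directions and was not tested. The biological explanation, that the enzymes act oppositely on these genes, stays open and untested too.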
